A study of Homo sapiens with 4 samples.

How the data were processed

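Mononuclear cells of 4 spleen samples from people with marginal zone lymphoma, an indolent B cell cancer, were measured by CITE-seq, which counts RNA and antibody-bound oligonucleotide tags in the same cells. The labels give 1 sample per patient, all in batch 1, with no treatment and no comparison group. The samples are called replicates 1 to 4 after the patient numbers in the labels. Expression was therefore compared between classes of cells inside the samples, with the sample as a block. Single samples were set against the other 3, and the spread between samples was measured, only to find values that stand apart.

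The files hold raw UMI counts per feature and barcode as deposited, in a filtered feature-barcode matrix per sample with 33538 genes and 73 antibody features. The counts were deposited without normalization. The authors' processing is known only in part: Seurat is named per the submitters' processing notes, with no version and no role. The aligner, the counter and the genome build are not given in the sources used here, and no genome was used, so no coordinates are printed and genes carry the symbols of the files. Per the labels' protocols, cells were incubated with 35 TotalSeq-C antibodies, and the labels also describe a bulk RNA extraction kit. The deposited matrices hold more antibody features than the labels state, and the difference could not be settled from the files. Because barcodes were filtered before deposit, empty droplets could not be used to estimate free RNA. XIST, TSIX and Y-linked genes, 91 in all, were removed, which left 33447 genes. The files give 48 gene symbols to more than 1 gene, and such genes were kept apart.

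Depth was 22887361, 48492420, 31540260 and 20203197 RNA UMIs in replicates 1 to 4, with 19248119, 18529040, 20367282 and 9002833 antibody counts. Of 22993 barcodes, those with at least 300 genes and at most 15% mitochondrial UMIs passed. Scrublet in scanpy 1.11.5 then called 83 of 15625 cells (0.531%) doublets, and these were removed. It called 5, 5, 18 and 55 cells (0.13%, 0.112%, 0.587% and 1.295%) in replicates 1 to 4, where an expected rate of 0.8% per 1000 barcodes gives 158, 186, 183 and 177. That rate, which removes 704 cells, was therefore added as an alternative after the data had been seen. Kept cells numbered 15542.

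Antibody gates were set on the per-cell centred log ratio, with a 2-component Gaussian mixture per sample (scikit-learn 1.9.0) for CD3, CD4, CD8 and an antibody of the B cell gate that is not reported here. T cells were positive for CD3 and negative for that antibody, and B cells the reverse. CD4 T cells were CD4+CD8- and CD8 T cells CD8+CD4-. PD-1 high and low cells were the highest and lowest tertile of the PD-1 antibody in their class and sample. CD25 high CD127 low cells lay above the 90th percentile of CD25 and below the median of CD127 among the CD4 T cells of their sample. In the tests, RNA was compared only between classes gated on protein, and protein only between classes named from RNA. The correlation of RNA with protein differences was not tested and took both between classes named from RNA, so its RNA differences include genes that defined the classes. Protein gates were its alternative. Genes encoding an antibody target of the gate were left out of the list tests and of the named genes.

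RNA UMI counts were summed per sample and class, with at least 20 cells per sum. Sums were tested with edgeR 4.0.16 (R 4.3.3): filterByExpr, TMM factors, the quasi-likelihood test with the sample as a block, and Benjamini-Hochberg adjustment at 0.05. Every adjusted p of a single gene below comes from that test. The PD-1 effects in CD8 and CD4 T cells were compared by an interaction term. CPM levels are means and SDs over 4 samples. Both classes of a comparison come from the same patient, so the numbers pair the sums. Deviations of the sums from their class means correlated within every pair: 0.31 to 0.55 for CD8 and CD4, 0.44 to 0.6 for PD-1 in CD4, 0.21 to 0.58 for PD-1 in CD8, 0.33 to 0.43 for CD25 and 0.32 to 0.42 for B and T cells.

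The rule for named genes took, per comparison, the 10 highest and 10 lowest log2 fold changes. It required an adjusted p under 0.05, a mean of at least 50 CPM in the higher class and the same sign in every sample. Gate genes, immunoglobulin, T cell receptor, mitochondrial, ribosomal protein, HLA-DRB, metallothionein and unnamed genes were left out of that choice. From each fixed list, the members with the lowest adjusted p are also named. The 23 lists cover checkpoint receptors, checkpoint ligands, costimulatory receptors, cytotoxic effectors, T follicular helper, regulatory T, naive and central memory T, exhaustion transcription factors, tissue residency, chemokine receptors, chemokines and cytokines, interferon response, immediate early and heat shock, cell cycle, MHC class II presentation, NF-kB targets, B cell receptor signalling, marginal zone and memory B, naive B, germinal centre B, plasma cell programme, heavy chain isotypes and B cell survival. Each list with at least 5 tested genes was tested on limma-voom values (limma 3.58.1) with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a comparison. The design, the lists, the markers of 20 cell types, the naming rule and most alternatives were fixed before the data were examined.

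For RNA classes, 2000 variable genes without immunoglobulin and T cell receptor genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (igraph 0.11.9) were used without integrating the samples. A cluster was called by a cell type only where at least 3 of its fixed markers were detected and its leading genes did not belong more to another type. Antibody levels per class were means of log2(counts per 10000 + 1), tested with limma, each class against the mean of the other classes, with the sample as a block and Benjamini-Hochberg adjustment over all antibody and class pairs. Correlations of RNA with protein are across antibodies, which are not replicates, and carry no p. Light chain was assigned to B cells with at least 10 light chain constant UMIs, at least 80% of them from one chain. Intervals of shares are 95% Wilson intervals, or exact ones for light chains. Ratios against a class with 1 to 3 counts carry exact 95% intervals that cover counting error only. With 4 samples, an exact two-sided sign-flip test cannot give a p below 1 in 8.

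Each test was tried on simulated data, with 200 genes changed by a log2 fold of 1 or 2 in counts drawn from the real means and library sizes. Genes with the lowest total counts were not among those changed, so the recovery is not known for them. The recovery at log2 1 and 2 was 74% and 100% for CD8 against CD4 (8271 genes) and 70% and 92% for PD-1 in CD4 (4969 genes). It was 86% and 88% for PD-1 in CD8 (4205 genes), 35% and 82% for the interaction (5890 genes) and 47% and 86% for CD25 high CD127 low cells (4956 genes). For B against T cells it was 2% and 81% (11097 genes). False calls numbered 6, 9, 11, 11, 10 and 7. Of antibodies shifted by 0.5 in CD4 T-like cells, 55% were recovered by limma, with 0 false calls in that class. False calls in the other classes were not counted.

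Alternatives were DESeq2 1.42.0, RLE factors, no low count filter, no replicate block, a stricter cell filter of 500 genes and 10% mitochondrial UMIs, doublets kept, doublets by expected rate, Otsu gates (scikit-image 0.26.0), equal cell numbers, other PD-1 and CD25 splits, a centred log ratio for antibodies, Leiden resolutions 0.5 and 2, and leaving out each sample. Levels of single genes within the immunoglobulin and T cell receptor loci are not given per sample. HLA class II genes and genes with near-identical copies may share reads, and their counts are uncertain to that extent. Such copies exist for CCL3 and for CCL4, each on its own, for XCL1 with XCL2 and among the IGHG genes. The other packages were Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.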

Results

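Mononuclear cells from the spleens of 4 people with marginal zone lymphoma were profiled by CITE-seq to describe RNA and surface protein in the tumor and in the immune cells around it. The 4 samples form 1 group and 1 batch. Depth was 22887361 RNA UMIs in replicate 1, 48492420 in replicate 2, 31540260 in replicate 3 and 20203197 in replicate 4. The files held 5140, 5187, 7465 and 5201 barcodes, of which 3832, 4472, 3047 and 4191 were kept as cells. More than 15% of UMIs were mitochondrial in 58.94% of the barcodes of replicate 3, against 13.61% to 25.35% in the other samples. Kept cells had a median of 5106.5, 9586.5, 6060 and 3737 RNA UMIs. The labels give no groups of people to compare.

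Cell composition was examined first with surface protein. B cells gated on antibody counts made up 62.48% ± 13.35 (SD, n = 4) of cells and T cells 20.09% ± 7.05. CD4 T cells were 9.74% ± 1.57 of cells and CD8 T cells 8.96% ± 5.49. The B cell share ran from 49.03% in replicate 4 (95% Wilson interval 47.52 to 50.55) to 80.56% in replicate 1 (79.28 to 81.78). The CD4 to CD8 T cell ratio averaged 1.58 ± 1.26 and was 3.44 in replicate 1, without which the mean was 0.96. The CD8 share was on average -0.78 ± 4.42 percentage points from the CD4 share, a difference within the spread between samples (exact two-sided sign-flip permutation test, p = 0.75, n = 4; 1 in 8 is the smallest p it can give). Among barcodes left out for a high mitochondrial share, T cells made up 7.21%, 7.22%, 5.32% and 29.47% in replicates 1 to 4, against 12.58%, 16.3%, 23.07% and 28.42% of kept cells.

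**Figure D1:**
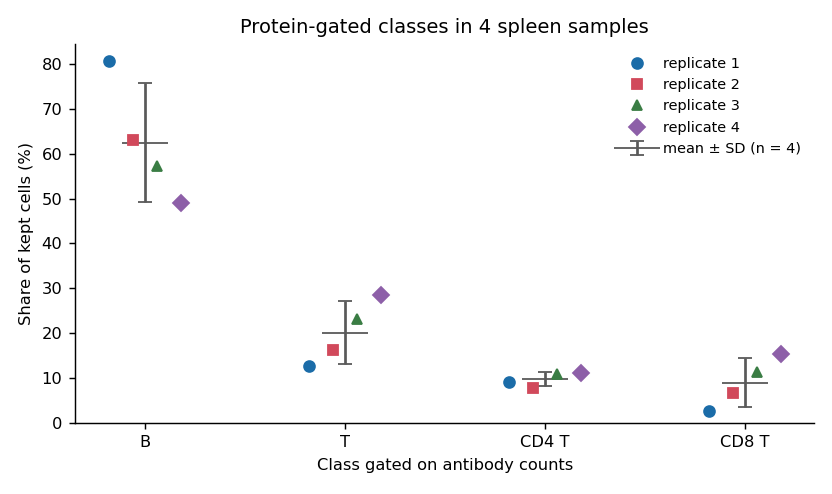
Share of kept cells (%, y axis) in each class gated on antibody counts (x axis), 1 point per sample with the mean and SD of 4 samples. B cells were the most frequent class in each sample, from 49.03% to 80.56%, and the CD4 T cell share varied less (SD 1.57) than the CD8 T cell share (SD 5.49).

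Clustering on RNA gave 23 clusters. B-like cells made up 47.09% ± 34.46 of cells (n = 4), CD8 T-like cells 11.01% ± 5.26, CD4 T-like cells 8.23% ± 2.47, NK-like cells 4.47% ± 4.1 and regulatory T-like cells 1.83% ± 0.6. The B-like share of replicate 2 was only 0.09%, since 71.42% of its cells (95% Wilson interval 70.08 to 72.73) fell in 2 clusters that the fixed markers did not name. These clusters were led by ATF5, JCHAIN, CCL22, MIR155HG and CXCL10, and no other sample had cells there. By surface protein, 63.01% of the cells of replicate 2 were B cells. Of all protein-gated B cells, 67.46% were B-like and 26.45% were in the unnamed clusters. Monocyte and macrophage-like cells averaged 4.39% ± 5.15, and 1.83% without replicate 4. Plasma-like cells averaged 1.43% ± 1.8, and 0.53% without replicate 2. Cycling-like cells averaged 3.7% ± 5.22, and 1.17% without replicate 3. Of the protein-gated CD4 T cells, 70.66% were CD4 T-like and 17.05% regulatory T-like. Among CD8 T cells 87.26% were CD8 T-like and 0.8% NK-like.

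Surface protein was then compared across the 7 classes named from RNA that had at least 20 cells in at least 3 samples, which leaves out cycling-like cells. CD20 (log2 difference from the mean of the other classes 2.98 ± 0.3 SE, adjusted p = 7.75e-08, n = 3), CD22 (2.82 ± 0.23) and HLA-DR (2.29 ± 0.25) were higher in B-like cells, with the same sign in 3 of 3 samples by limma. CD8 stood out in CD8 T-like cells (3.81 ± 0.21, adjusted p = 1.65e-11, 4 of 4 samples), which also had more CD57 (1.44 ± 0.15), a marker of late differentiation. Regulatory T-like cells had more CD4 (2.93 ± 0.16), the costimulatory receptor CD278 (2.24 ± 0.18), the inhibitory receptor TIGIT (1.51 ± 0.15), CD25 (1.35 ± 0.21) and PD-1, listed as CD279 (1.01 ± 0.15). CD4 T-like cells also had more PD-1 (1.09 ± 0.15, adjusted p = 4.42e-06), whereas in CD8 T-like cells PD-1 did not pass (0.33 ± 0.15, adjusted p = 0.074, limma, 3 of 4 samples). NK-like cells led in CD7 (3.6 ± 0.26) and CD56 (3.51 ± 0.26), and monocyte and macrophage-like cells in CD36 (4.13 ± 0.24), CD11c (3.63 ± 0.25) and the Fc receptor CD64 (3.5 ± 0.3). Plasma-like cells led in CD38 (3.96 ± 0.42), while CD138, the usual plasma cell antigen, was lower in them (-0.31 ± 0.13, adjusted p = 0.045, limma). On this scale, which is relative to the antibody total of each cell, 48 of 72 antibodies were lower in plasma-like cells and 6 higher. The fall is therefore not particular to CD138.

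In all, 250 of 504 antibody and class pairs passed, 106 of them higher and 144 lower. The anti-PE antibody, which binds no cell antigen of its own, was higher in monocyte and macrophage-like cells (2.95 ± 0.18, adjusted p = 6.23e-11, limma, 4 of 4 samples), and the anti-FITC antibody in CD4 T-like (1.62 ± 0.17, adjusted p = 1.04e-07, limma, 4 of 4) and regulatory T-like cells (1.82 ± 0.17, 4 of 4). B-, NK- and plasma-like cells entered from 3 samples only, since 1 sample had fewer than 20 such cells. Without the replicate block 122 pairs passed.

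**Figure D2:**
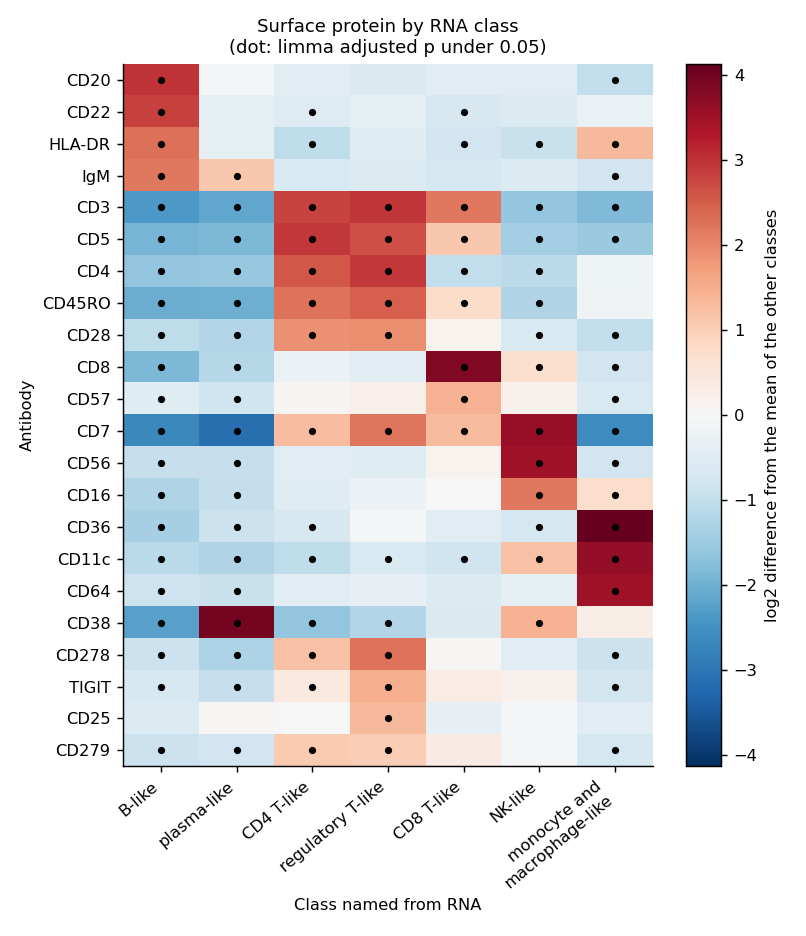
Difference of each antibody (y axis) in each RNA class (x axis) from the mean of the other classes, as log2 of counts per 10000 + 1 on a colour scale, with a dot where limma's adjusted p was under 0.05. The darkest red cells are CD36 (4.13), CD11c and CD64 in monocyte and macrophage-like cells, CD38 (3.96) in plasma-like cells, CD8 (3.81) in CD8 T-like cells, and CD7 and CD56 in NK-like cells.

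RNA and protein differences between B-like and T-like cells were set beside each other for 50 antibodies. They went the same way for 39, with a Spearman rho across antibodies of 0.87 over 3 samples. These classes were named from RNA, and between protein-gated B and T cells rho was 0.843 over 46 antibodies and 4 samples. CD23 (FCER2), a receptor for IgE, was among those that did not: its RNA was 4.46 log2 units higher in B-like cells and its antibody -0.31. CD26 (DPP4) RNA differed by -4.19 and its antibody by 0.51 ± 1.11 (SD), with the same sign in 1 of 3 samples. CD80, a ligand of CD28 and CTLA4, differed by 2.06 in RNA and -0.5 in protein. Antibodies whose gene was not counted as detected in either class lay between -0.78 (CD36) and 0.19 (CD10). The antibody values of CD23 and CD80 lie in that range, so they do not show less of these proteins on B-like cells. At least 1 UMI of CD3E was found in 94.99% ± 0.5 of gated T cells (n = 4; median 3182 UMIs) and in 0.69% of gated B cells (median 6780 UMIs). CD8A was found in 90.83% ± 0.51 of CD8 T cells but CD4 in only 39.17% ± 6.76 of CD4 T cells, against 0.2% and 0.21% of B cells. Thinned to 1000 UMIs per cell, which left out 63 T cells and 15 B cells, CD3E was found in 71.85% ± 7.83, CD8A in 67.02% ± 4.88 and CD4 in 13.62% ± 3.4. MS4A1, which encodes CD20, was found in 92.75% ± 12.58 of B cells and 8.68% of T cells, and in 68.9% ± 25.45 of B cells after thinning.

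**Figure D3:**
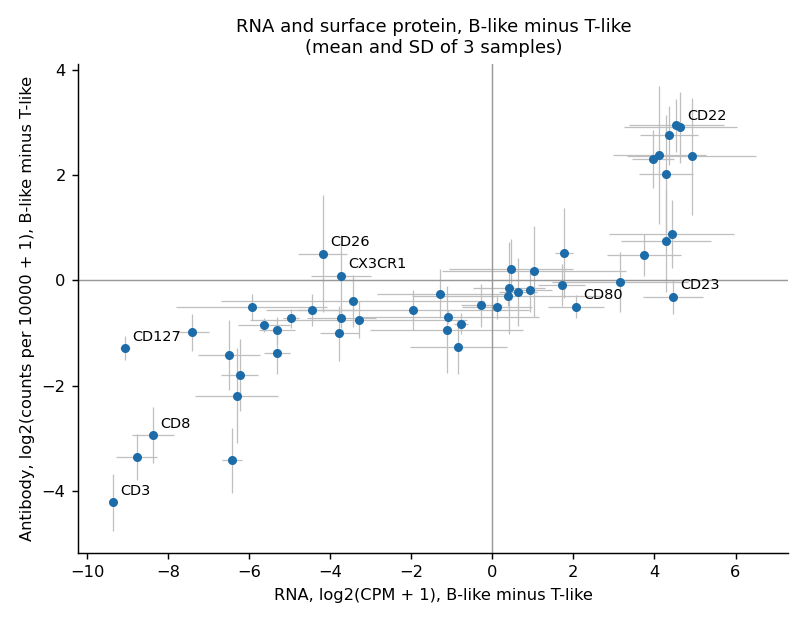
Difference in RNA (x axis, log2(CPM + 1)) against difference in antibody level (y axis, log2(counts per 10000 + 1)) between B-like and T-like cells, 1 point per antibody, mean and SD of 3 samples. Most points lie in the lower left and upper right quadrants (39 of 50 have the same sign), and CD23 and CD26 lie off that diagonal.

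CD8 and CD4 T cells gated by surface protein were compared to describe their programmes in the lymphoma spleen. CD8 T cells had far more RNA of the killing machinery: NKG7, a cytotoxic granule protein, was at 3168 ± 865 CPM (SD, n = 4) against 222 ± 159 in CD4 T cells, and the chemokine CCL5 at 3561 ± 735 against 348 ± 249. CD4 T cells had more CD40LG, the helper signal to B cells (173 ± 126 against 4.99 ± 2.52 CPM), and more FOXP3, the master factor of regulatory T cells (143 ± 91 against 3.59 ± 3.81 CPM). By edgeR 519 of 8486 genes passed, 236 higher and 283 lower in CD8 T cells, and 496 of them had the same sign in all 4 samples. The genes furthest up were KLRD1 (log2 fold change 5.01 ± 0.39 SE, adjusted p = 2.35e-05), CRTAM (4.15 ± 0.32), NKG7 (4.02 ± 0.39), FCGR3A, XCL2, PECAM1, CCL5, GZMH, GZMB and CCL4 (3.34 ± 0.38). Furthest down were FBLN7 (-5.38 ± 0.34, adjusted p = 5.57e-06), TSHZ2 (-5.16 ± 0.34), CD40LG (-4.99 ± 0.32), FOXP3 (-4.98 ± 0.25), TNFRSF4, IL6R, TNFRSF18, ICA1, IL2RA and SMCO4 (-3.17 ± 0.37). Each of these had the same sign in 4 of 4 samples. In replicate 2, CD4 T cells also held cytotoxic RNA: NKG7 was at 458 CPM there against 100 to 166 in the other samples, and GNLY at 1557 CPM, with 1 count of CD8A. Without the replicate block 105 genes passed and without replicate 3 there were 281.

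All 13 cytotoxic effectors tested rose in CD8 T cells, and also when adjusted over the list alone (13), among them CST7 (2.57 ± 0.15), GZMA (2.93 ± 0.23) and PRF1 (2.52 ± 0.21). The list was up by limma's camera (adjusted p = 7.47e-25, and adjusted p = 0.068 with an estimated correlation). Of the NK cell markers 9 of 10 also rose, and of the gamma delta T cell markers 3 of 4 (TRGC2 42.8 ± 38.1 against 3.52 ± 1.02 CPM). Among the regulatory T genes 9 of 12 fell (10 adjusted over the list alone; FOXP3, TNFRSF18 -4.02 ± 0.22; limma's camera adjusted p = 5.72e-15, adjusted p = 0.114 with an estimated correlation). Costimulatory receptors fell in 8 of 11 (8 adjusted over the list alone), with TNFRSF4 at -4.52 ± 0.28 and SLAMF1 at -1.67 ± 0.18 (limma's camera adjusted p = 2.35e-10, adjusted p = 0.143 with an estimated correlation). Naive and central memory T genes fell in 7 of 13 and rose in 1 (9 and 1 adjusted over the list alone): TCF7 was lower (-1.62 ± 0.14) and PECAM1, an adhesion molecule, higher (3.72 ± 0.23; limma's camera adjusted p = 2.65e-06, adjusted p = 0.234 with an estimated correlation). In the T follicular helper list 4 of 11 fell (7 adjusted over the list alone), including PASK (-1.80 ± 0.19) and ICOS (-1.89 ± 0.27; limma's camera adjusted p = 6.35e-05, adjusted p = 0.211 with an estimated correlation). MHC class II presentation genes rose in 4 of 7 (5 adjusted over the list alone), such as HLA-DPA1 (1.11 ± 0.20) and CD74 (0.63 ± 0.15; limma's camera adjusted p = 8.42e-06, adjusted p = 0.279 with an estimated correlation).

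Chemokines and cytokines split, with 6 of 12 up and 2 down (7 and 4 adjusted over the list alone): XCL2 rose by 3.93 ± 0.36 and LTB fell by 1.64 ± 0.16 (limma's camera up, adjusted p = 0.0276, adjusted p = 0.234 with an estimated correlation). PLCG2 (1.53 ± 0.26) and PIK3AP1 (2.51 ± 0.44) were the 2 of 9 B cell receptor signalling genes that rose (3 adjusted over the list alone), both of them also used outside B cells (limma's camera adjusted p = 0.0224, adjusted p = 0.279 with an estimated correlation). HERPUD1 (0.71 ± 0.12) and FKBP11 (1.06 ± 0.21), genes of protein folding and secretion, were the 2 of 8 plasma cell programme genes that rose (2 adjusted over the list alone; limma's camera adjusted p = 0.00293, adjusted p = 0.234 with an estimated correlation). Checkpoint receptors had 3 of 11 up and 4 down (3 and 5 adjusted over the list alone): LAG3 (3.21 ± 0.22) and CD244 (3.87 ± 0.43) were higher, BTLA (-2.04 ± 0.22) and PDCD1 (-1.14 ± 0.18) lower. For this list the median (-0.41) and the mean (0.24) differ in sign and camera, pointing down, did not call it. The same holds for the exhaustion transcription factors (-0.04 and 0.13), NF-kB targets (-0.17 and 0.02) and naive B genes (-0.09 and 0.1). For chemokine receptors the median (-0.06) and the mean (-0.1) were below 0 and fry pointed up, without a call. In the exhaustion list EOMES rose (3.23 ± 0.20) and BATF fell (-0.92 ± 0.15), 2 genes each way (3 and 4 adjusted over the list alone). CXCR6 (2.00 ± 0.26) and CX3CR1 (2.10 ± 0.33) were among 3 chemokine receptors that rose, and GPR183 (-1.31 ± 0.20) among 3 that fell, of 12 (3 and 4 adjusted over the list alone). NF-kB targets had 2 of 14 up and 2 down (2 and 5 adjusted over the list alone), naive B genes 2 of 7 each way (2 and 3). B cell survival had 2 of 9 down (PIM2 -1.08 ± 0.14; 2 adjusted over the list alone), marginal zone and memory B 3 of 6 up (FCRL3 1.60 ± 0.18; 3 up and 1 down). Tissue residency had 1 of 8 up (2 adjusted over the list alone), germinal centre B 1 of 4 up (2) and checkpoint ligands 1 of 3 down (CD200 -1.82 ± 0.36; 2 adjusted over the list alone). Members of the cell cycle, interferon response, immediate early and heat shock, and heavy chain isotype lists did not pass. By fry 6 lists of 20 passed.

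PD-1 high and PD-1 low CD4 T cells were compared to find what marks CD4 T cells that carry this inhibitory receptor. CXCL13, the chemokine that draws B cells into follicles, had the largest fold change: 2279 ± 2049 CPM (SD, n = 4) against 1.94 ± 2.24, or 4847 against 3 counts, a ratio of 1646 (exact 95% interval 562.8 to 7983, counting error only). It was 1201, 3424, 4745 and 34.8 CPM in PD-1 high cells of replicates 1 to 4. TOX, a transcription factor of chronically stimulated T cells, was at 116 ± 24.4 against 34.4 ± 23.5 CPM, and CXCR5, the receptor for CXCL13, at 67 ± 22.3 against 23.8 ± 16.2. FOXP3 was lower in PD-1 high cells (68.9 ± 47 against 202 ± 124 CPM). By edgeR 79 of 5272 genes passed, 33 higher and 46 lower, 76 with the same sign in all samples. Genes furthest up after CXCL13 (10.26 ± 0.32, adjusted p = 5.52e-10) were CHI3L2 (2.05 ± 0.29, adjusted p = 0.00366), THADA, FABP5, TOX (1.94 ± 0.31), ITM2A, AHI1, SH2D1A (1.68 ± 0.26), CXCR5 (1.58 ± 0.28) and SLC9A9 (1.56 ± 0.27). Furthest down were PTGER2 (-2.42 ± 0.40, adjusted p = 0.00889), CISH (-2.33 ± 0.35), CD55, CAPG, CTSW, MGAT4A, FLT3LG, IL2RA (-1.62 ± 0.24), FKBP11 and FOXP3 (-1.56 ± 0.35), each in 4 of 4 samples. The count was 20 without replicate 1, 18 without replicate 2 and 190 without replicate 4. Without the replicate block only 1 gene passed, by DESeq2 49, and 44 among cells above the median of CD45RO.

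**Figure D4:**
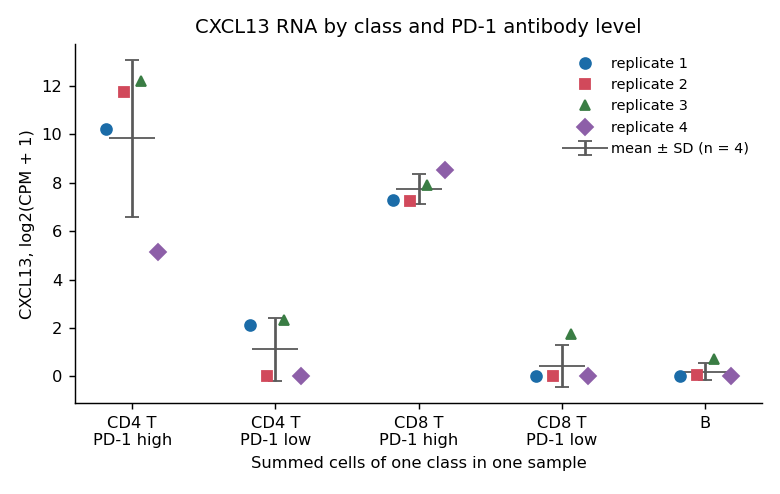
CXCL13 RNA as log2(CPM + 1) (y axis) in summed cells of each class (x axis), 1 point per sample with the mean and SD of 4 samples. PD-1 high CD4 and CD8 T cells lie above the PD-1 low cells and the B cells of every sample, and in replicate 4 the CD8 value (373 CPM) exceeds the CD4 value (34.8 CPM).

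T follicular helper genes, which guide help to B cells, rose in 5 of 6 (5 adjusted over the list alone): CXCL13, PASK (1.49 ± 0.17), SH2D1A and CXCR5 (limma's camera adjusted p = 1.78e-11, adjusted p = 0.163 with an estimated correlation). Naive and central memory T genes fell in 4 of 12 (10 fell and 1 rose adjusted over the list alone), among them KLF2 (-1.38 ± 0.23) and IL7R (-1.06 ± 0.19; limma's camera adjusted p = 4.48e-07, adjusted p = 0.222 with an estimated correlation). MHC class II presentation genes were down (limma's camera adjusted p = 4.64e-07, adjusted p = 0.222 with an estimated correlation), with 1 of 5 past the test, HLA-DRA (-1.42 ± 0.22), and 5 adjusted over the list alone. Further lists were down with few or no single genes past the test. Immediate early and heat shock genes had a median of -0.31 (3 of 15 fell adjusted over the list alone; DUSP1 -0.61 ± 0.15, adjusted p = 0.0761; limma's camera adjusted p = 0.000322, adjusted p = 0.233 with an estimated correlation). Interferon response genes had a median of -0.44 over 9 genes, with OAS1 at -0.77 ± 0.27 (limma's camera adjusted p = 0.000322, adjusted p = 0.233 with an estimated correlation). FKBP11 (-1.62 ± 0.26) was the 1 of 6 plasma cell programme genes that fell (4 adjusted over the list alone; limma's camera adjusted p = 0.00652, adjusted p = 0.222 with an estimated correlation). PIM1 (-1.03 ± 0.18) was the 1 of 9 B cell survival genes that fell (2 adjusted over the list alone; limma's camera adjusted p = 0.013, adjusted p = 0.222 with an estimated correlation). Costimulatory receptors were up (median 0.34; CD27 0.61 ± 0.15, adjusted p = 0.0761; 2 of 10 adjusted over the list alone; limma's camera adjusted p = 0.00749, adjusted p = 0.222 with an estimated correlation). So were the exhaustion transcription factors, where TOX was the 1 of 7 that rose (4 up and 2 down adjusted over the list alone; limma's camera adjusted p = 0.0366, adjusted p = 0.233 with an estimated correlation).

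In the regulatory T list TIGIT rose (1.08 ± 0.17) and IL2RA and FOXP3 fell, of 11 (2 up and 4 down adjusted over the list alone). Its median was 0.24 and its mean -0.31, and camera, pointing down, did not call it. For chemokines and cytokines the median was -0.64 and the mean, raised by CXCL13, was 0.72, with camera pointing down and no call. LTB was the 1 of 9 that fell (-0.95 ± 0.17; 2 up and 4 down adjusted over the list alone). TIGIT was also the 1 of 8 checkpoint receptors that rose (2 up and 1 down adjusted over the list alone). CTSW was the 1 of 11 cytotoxic effectors that fell (3 up and 4 down adjusted over the list alone). CXCR5 rose and S1PR1, which lets T cells leave tissue, fell (-1.51 ± 0.29) among 8 chemokine receptors (1 each way adjusted over the list alone), and IL4R fell (-1.27 ± 0.28) among 5 naive B genes (2 adjusted over the list alone). No member of the cell cycle, NF-kB target, tissue residency, checkpoint ligand, B cell receptor signalling, marginal zone and memory B, germinal centre B or heavy chain lists passed edgeR's test. Adjusted over the list alone, 1 of 7 tissue residency genes rose and 3 fell, and 1 of 4 marginal zone and memory B genes rose. By fry none of 18 lists passed (lowest adjusted p = 0.0511, T follicular helper), against 9 by limma's camera at the preset correlation.

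**Figure D5:**
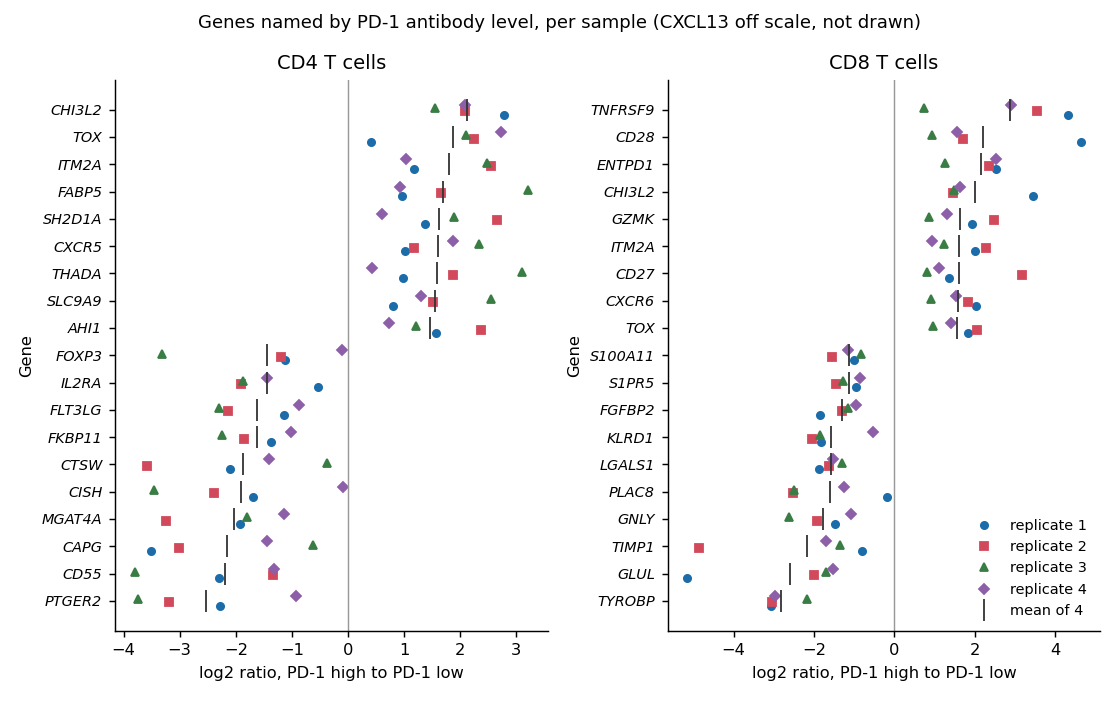
log2 ratio of PD-1 high to PD-1 low cells (x axis) for the genes named in CD4 (left) and CD8 T cells (right), 1 point per sample with a bar at the mean of 4; CXCL13 is off the scale and not drawn. Each gene lies on one side of 0 in all 4 samples, with FOXP3 and CISH of replicate 4 in CD4 and PLAC8 of replicate 1 in CD8 T cells nearest to 0.

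The same split was made in CD8 T cells. PD-1 high CD8 T cells also had more CXCL13 (244 ± 132 against 0.6 ± 1.19 CPM, n = 4), with 399 counts against 1 and a ratio of 445.6 (exact 95% interval 79.52 to 17640, counting error only). In the same cells CD40LG had 0 counts in each sample, and the 9 genes far higher in CD4 than in CD8 T cells stood at a median of 0%, 4.46%, 6.1% and 7.57% of their PD-1 high CD4 level in replicates 1 to 4. CXCR6, a chemokine receptor of tissue T cells, was at 258 ± 138 against 84.2 ± 46.3 CPM, and GZMK, a granzyme, was also higher. GNLY, which encodes a cytotoxic granule protein, was lower (1117 ± 783 against 3229 ± 1882 CPM). By edgeR 41 of 4576 genes passed, 22 higher and 19 lower, 40 with the same sign in all samples. Those furthest up after CXCL13 (8.09 ± 0.41, adjusted p = 6.43e-08) were TNFRSF9 (1.98 ± 0.43, adjusted p = 0.0446), ENTPD1 (1.96 ± 0.35), CHI3L2, GZMK (1.59 ± 0.21), CD27, TOX (1.52 ± 0.26), CXCR6, CD28 and ITM2A (1.46 ± 0.21). Those furthest down were TIMP1 (-3.00 ± 0.47, adjusted p = 0.00517), TYROBP (-2.80 ± 0.22), GLUL, PLAC8, GNLY (-1.72 ± 0.19), LGALS1, KLRD1 (-1.39 ± 0.23), S100A11, FGFBP2 and S1PR5 (-1.13 ± 0.23), each in 4 of 4 samples. TYROBP, GNLY and KLRD1 are also markers of NK cells, and 3 of 11 NK markers fell in all, while NKG7 was at 3415 ± 856 against 3810 ± 1392 CPM (adjusted p = 0.918, edgeR, 2 of 4 samples). The myeloid marker CST3 was at 18.3 ± 15.5 against 69.4 ± 67.7 CPM (adjusted p = 0.0841, edgeR, 3 of 4 samples). Replicate 1 entered with 34 cells in each class. Without the replicate block 2 genes passed, and 2 among cells above the median of CD45RO, which left 3 samples.

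Checkpoint receptors rose in 3 of 8 (5 up and 1 down adjusted over the list alone): TIGIT (1.1 ± 0.18), ENTPD1 and CTLA4 (1.96 ± 0.36; limma's camera adjusted p = 0.0019, adjusted p = 0.287 with an estimated correlation). CD27, CD28 and TNFRSF9 were the 3 of 4 costimulatory receptors that rose (3 adjusted over the list alone), too few for a list test. Naive and central memory T genes were down, IL7R (-0.98 ± 0.15) being the 1 of 12 that passed (6 adjusted over the list alone; limma's camera adjusted p = 4.21e-06, adjusted p = 0.287 with an estimated correlation). MHC class II presentation was up with HLA-DMA (0.91 ± 0.20), 1 of 6 (1 adjusted over the list alone; limma's camera adjusted p = 0.00274, adjusted p = 0.287 with an estimated correlation). The cell cycle list was up with a median of 0.57 and no single gene past the test (1 of 5, HMGB2 0.46 ± 0.15, adjusted over the list alone; limma's camera adjusted p = 0.00274, adjusted p = 0.287 with an estimated correlation). Immediate early and heat shock genes were down (median -0.22; JUN -0.55 ± 0.14; 4 of 14 adjusted over the list alone; limma's camera adjusted p = 0.00274, adjusted p = 0.335 with an estimated correlation). In the regulatory T list TIGIT and CTLA4 rose, 2 of 5 (2 adjusted over the list alone; limma's camera adjusted p = 0.00393, adjusted p = 0.287 with an estimated correlation), both also checkpoint receptors.

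Cytotoxic effectors split in PD-1 high CD8 T cells. GZMK and GZMA (0.66 ± 0.14) rose and GNLY and KLRD1 fell, of 13 (4 up and 5 down adjusted over the list alone), and camera did not call the list. CXCR6 and RGS1 (1.34 ± 0.23) were the 2 of 7 tissue residency genes that rose (2 up and 1 down adjusted over the list alone; ZNF683 was at -1.74 ± 0.40, adjusted p = 0.0646). TOX was the 1 of 7 exhaustion transcription factors that rose, CXCL13 the 1 of 4 T follicular helper genes (2 adjusted over the list alone, with SH2D1A 0.87 ± 0.21) and the 1 of 11 chemokines and cytokines. For this last list the median (-0.28) and the mean (0.47) differ in sign, with camera pointing down and no call. CXCR6 was the 1 of 8 chemokine receptors and CD27 the 1 of 4 marginal zone and memory B genes that rose. Adjusted over the list alone, exhaustion transcription factors and chemokines and cytokines had 1 up, and chemokine receptors, marginal zone and memory B genes and naive B genes 1 each way. Members of the interferon response, NF-kB target, B cell receptor signalling, B cell survival, plasma cell programme, naive B, germinal centre B, heavy chain and checkpoint ligand lists did not pass (2 plasma cell programme genes and 1 NF-kB target fell adjusted over the list alone). The plasma cell programme (median 0.01, mean -0.05, camera down without a call) and the marginal zone and memory B list (-0.21 and 0.05, too few genes for a test) also differ in sign. By fry none of 16 lists passed, against 6 by limma's camera at the preset correlation.

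Whether the PD-1 difference itself differed between CD8 and CD4 T cells was tested by the interaction. No gene of 6111 passed by edgeR (0, with 337 at an unadjusted p under 0.05), and 1 passed by DESeq2. Among the genes of the fixed lists CXCR6 had the lowest p: it was 1.58 log2 units higher in PD-1 high CD8 T cells and -0.99 in PD-1 high CD4 T cells (interaction 2.48 ± 0.47, adjusted p = 0.108, 4 of 4 samples). TNFRSF9 (4.13 ± 0.87, adjusted p = 0.167), HLA-DMA (1.68 ± 0.39, adjusted p = 0.256), TCF7 (-1.37 ± 0.34, adjusted p = 0.284), CD226 (-2.40 ± 0.60, adjusted p = 0.297) and ENTPD1 (2.26 ± 0.59, adjusted p = 0.319) came next among those genes and did not pass edgeR's test. Without replicate 1 the count was 1, without replicate 3 it was 3 and without replicate 4 it was 2, and comparing the highest with the lowest quartile of PD-1 gave 4.

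At the level of lists, limma's camera called 6 of 20 at the preset correlation. The PD-1 log2 fold change was more positive in CD8 than in CD4 T cells for MHC class II presentation, whose medians were 0.38 in CD8 and -0.77 in CD4 T cells (interaction median 1.11; 4 of 7 adjusted over the list alone; limma's camera adjusted p = 1.33e-06, adjusted p = 0.292 with an estimated correlation). The interaction was also positive for chemokine receptors, at 0.07 in CD8 and -0.4 in CD4 T cells (interaction median 0.5; limma's camera adjusted p = 0.0243, adjusted p = 0.292 with an estimated correlation). For the plasma cell programme the medians were 0.01 and -0.68 (interaction median 0.52; limma's camera adjusted p = 0.0399, adjusted p = 0.292 with an estimated correlation). Cell cycle genes had medians of 0.57 and 0.03 (interaction median 0.46) and interferon response genes -0.06 and -0.44 (0.38), each with limma's camera adjusted p = 0.0399 and adjusted p = 0.382 with an estimated correlation. For T follicular helper genes the interaction was negative, with medians of 0.58 in CD8 and 1.54 in CD4 T cells (interaction median -1.12; PASK -1.17 ± 0.41; limma's camera adjusted p = 0.0162, adjusted p = 0.284 with an estimated correlation). Costimulatory receptors had a median of -0.23 and a mean of -0.14 with camera pointing up and no call, and marginal zone and memory B genes -0.14 and 0.01 with camera pointing down and no call. Adjusted over the list alone, the interaction was positive for 1 of 10 chemokine receptors and for 2 genes each of the plasma cell programme, checkpoint receptors, chemokines and cytokines and tissue residency. It went both ways in costimulatory receptors (2 up and 3 down) and was negative for 1 of 13 naive and central memory T genes. By fry none of the 20 lists passed. Among the genes tested in both cell types, 6 rose in both PD-1 comparisons (CHI3L2, CXCL13, FABP5, ITM2A, TIGIT and TOX) and 4 fell in both (IL7R, LGALS1, S100A4 and S100A6), where independent lists of the same sizes would share 0.1 and 0.14. Of 63 genes past the test in CD4 T cells, 58 had the same sign in CD8 T cells (Pearson r across genes 0.87). Of 34 past the test in CD8 T cells, 27 had the same sign in CD4 T cells (r 0.82), against 2600 of all 4346 genes (r 0.39). Genes are not independent replicates, and both comparisons come from the same 4 people.

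CD25 high CD127 low cells were compared with the other CD4 T cells to describe cells with the surface phenotype of regulatory T cells. FOXP3 was at 679 ± 446 CPM (SD, n = 4) in them against 88.2 ± 45.5, and the inhibitory receptor CTLA4 at 290 ± 94.9 against 65.4 ± 10.5. IKZF2, which encodes the factor Helios, was at 162 ± 80.8 against 21.8 ± 13.3 CPM. NKG7 was lower (7.37 ± 10.6 against 264 ± 194 CPM), as was TCF7 (48.5 ± 50 against 271 ± 79.6 CPM), a factor of naive and memory T cells. By edgeR 183 of 5283 genes passed, 71 higher and 112 lower, 173 with the same sign in all samples. The genes furthest up were IL1R2 (3.81 ± 0.37, adjusted p = 0.000118), CCR8 (3.06 ± 0.41), FOXP3 (2.91 ± 0.17, adjusted p = 1.83e-06), IKZF2 (2.90 ± 0.31), HPGD, TTN, TNIP3, RTKN2, CTLA4 (2.15 ± 0.23) and LTA (2.13 ± 0.31). Those furthest down were NKG7 (-4.97 ± 0.37, adjusted p = 1.83e-05), ANXA1 (-4.74 ± 0.40), PLAC8, RBMS1, CD55, MGAT4A, CCL5 (-3.11 ± 0.43), CCL4, GZMB and KLF2 (-2.61 ± 0.46), each in 4 of 4 samples. PLAC8, CD55 and MGAT4A had 3 counts and RBMS1 2 in the CD25 high cells, which were 13.59-fold (exact 95% interval 4.62 to 66.19), 10.21-fold (3.462 to 49.79), 10.05-fold (3.406 to 48.99) and 12.36-fold (3.387 to 102.6) higher in the other cells. The class held only 24 to 35 cells per sample, and the count was 88 without replicate 1, 70 without replicate 2 and 110 without replicate 4. Without the replicate block 2 genes passed, and with equal cell numbers in both classes 62.

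All 11 regulatory T genes tested rose (11 adjusted over the list alone), TNFRSF18 by 1.90 ± 0.17 (limma's camera adjusted p = 9.98e-20, adjusted p = 0.117 with an estimated correlation). Cytotoxic effectors fell in 4 of 10 (8 adjusted over the list alone), including GZMA (-2.44 ± 0.44) and GZMH (-2.33 ± 0.50; limma's camera adjusted p = 2.41e-06, adjusted p = 0.257 with an estimated correlation). Naive and central memory T genes fell in 5 of 11 (7 adjusted over the list alone), such as TCF7 (-2.49 ± 0.43) and NOSIP (-1.21 ± 0.26; limma's camera adjusted p = 2.43e-06, adjusted p = 0.117 with an estimated correlation). Costimulatory receptors rose in 3 of 10 and CD40LG fell (4 and 1 adjusted over the list alone), with TNFRSF4 at 1.65 ± 0.18 and CD40LG at -1.97 ± 0.25 (limma's camera up, adjusted p = 0.0238, adjusted p = 0.304 with an estimated correlation). BCL2L1 (1.60 ± 0.27) and PIM2 (0.75 ± 0.16), which protect cells from death, were the 2 of 9 B cell survival genes that rose (2 adjusted over the list alone; limma's camera adjusted p = 0.0238, adjusted p = 0.442 with an estimated correlation). HLA-DRA (-1.35 ± 0.32) was the 1 of 5 MHC class II presentation genes that fell (2 adjusted over the list alone; limma's camera adjusted p = 0.0238, adjusted p = 0.405 with an estimated correlation).

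Checkpoint receptors rose in 3 of 9 (CTLA4, ENTPD1 1.64 ± 0.24, TIGIT 0.98 ± 0.16) and PDCD1 fell (-1.69 ± 0.39), with a median of -0.05, a mean of 0.28 and camera pointing up without a call. In the plasma cell programme PRDM1 rose (0.98 ± 0.23) and XBP1 and FKBP11 fell, of 7; its median was 0.28 and its mean -0.26, camera pointed down and fry up, and neither called it. Exhaustion transcription factors rose in 3 of 8 (IKZF2, PRDM1, BATF 1.00 ± 0.25). Tissue residency genes rose in 3 of 6 (CXCR6 1.75 ± 0.28, RGS1 1.07 ± 0.19), with CD69 down (-1.66 ± 0.28). Interferon response genes rose in 2 of 10 (ISG15 1.02 ± 0.22, IFI6 0.79 ± 0.19; 4 adjusted over the list alone). Chemokines and cytokines had 2 of 10 up, LTA among them, and 3 down. CXCL13 was among the latter (-4.66 ± 0.86, adjusted p = 0.0111, edgeR, 3 of 4 samples) and was also the 1 of 9 T follicular helper genes that fell. CXCR6 rose and S1PR1 fell (-2.60 ± 0.58) among 8 chemokine receptors (median -0.67, mean -0.52, fry pointing up without a call). Of 13 NF-kB targets CCL4 fell (-2.84 ± 0.32), while the median was 0.35 and camera pointed up without a call (3 up and 1 down adjusted over the list alone). CD27 rose (0.71 ± 0.18) among 3 marginal zone and memory B genes (2 adjusted over the list alone). Adjusted over the list alone, checkpoint receptors had 3 up and 1 down, the plasma cell programme 1 and 2, exhaustion transcription factors 3 and 0, tissue residency 3 and 1, chemokines and cytokines 2 and 4, T follicular helper genes 1 and 3 and chemokine receptors 1 and 2. Members of the cell cycle, immediate early and heat shock, B cell receptor signalling, checkpoint ligand and germinal centre B lists did not pass (1 B cell receptor signalling gene rose adjusted over the list alone). By fry 3 of 18 lists passed: regulatory T, costimulatory receptors, and naive and central memory T.

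Light chains were counted in B cells, since an excess of one light chain is the usual sign of a clone. The more frequent chain was carried by 98.92% of the assigned B cells in replicate 1 (exact 95% interval 97.51 to 99.65), 100% in replicate 2 (99.8 to 100), 100% in replicate 3 (99.38 to 100) and 74% in replicate 4 (64.27 to 82.26). By light chain antibody the share was 97.7%, 99.36%, 99.77% and 55.28%, so in replicates 2 and 4 it lay below the interval of the RNA share. Replicate 4 had at least 10 light chain UMIs in 105 of 2055 B cells, against 468 of 3087, 1872 of 2818 and 598 of 1746 in replicates 1 to 3. The intervals of the RNA share describe such cells only, and RNA and antibody are unlike measures. With 5, 0, 0 and 26 cells of the other chain, the planned comparison of both kinds of B cells could not be fitted.

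B and T cells gated by protein were compared to place chemokines, checkpoint molecules and their receptors in one compartment or the other. B cells had more CD79A, part of the B cell receptor (2271 ± 1366 CPM, SD, n = 4, against 40.1 ± 30.1), and more of the class II chains such as HLA-DPA1 (2921 ± 502 against 329 ± 117 CPM). T cells had CXCL13 at 462 ± 352 CPM against 0.17 ± 0.31 in B cells, whose receptor CXCR5 was higher in B cells (92.2 ± 34 against 25.5 ± 11.8 CPM). Of the checkpoint ligands, CD80 was higher in B cells (20.7 ± 25.6 against 2.69 ± 3.12 CPM) and the receptors CTLA4 and TIGIT higher in T cells (54 ± 16.7 against 0.19 ± 0.1 CPM for CTLA4). By edgeR 1731 of 11618 genes passed, 803 higher and 928 lower in B cells, 1718 with the same sign in all samples. The genes furthest up were TCL1A (6.51 ± 0.70, adjusted p = 0.00185), FCER2 (6.50 ± 0.43), VPREB3, LY86, DNASE1L3, BANK1, CD79A (5.74 ± 0.84), FAM129C, FCRLA and CR2 (5.58 ± 0.62). Those furthest down were CXCL13 (-11.92 ± 0.75, adjusted p = 0.000265), CD40LG (-10.03 ± 0.57), MAL, THEMIS, CD8B, CD28, TRAT1, CD8A, FOXP3 and IL7R (-9.07 ± 0.67), each in 4 of 4 samples. Among markers of other cell types, 3 of 5 of plasmacytoid dendritic cells rose in B cells (LILRA4 184 ± 202 against 3.95 ± 3.68 CPM, 3 of 4 samples). The count was 1015 without replicate 1, 1006 without replicate 3 and 1087 without replicate 4.

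Of the 15 lists that limma's camera called, 6 were up in B cells. B cell receptor signalling rose in 13 of 14 genes (14 adjusted over the list alone; CD79B 3.96 ± 0.41, SYK 4.87 ± 0.60; limma's camera adjusted p = 4.46e-11, adjusted p = 0.135 with an estimated correlation). MHC class II presentation rose in 9 of 9 (9 adjusted over the list alone; HLA-DMB 3.69 ± 0.28, CIITA 3.40 ± 0.37; limma's camera adjusted p = 5.41e-10, adjusted p = 0.0924 with an estimated correlation). Heavy chain isotypes rose in 6 of 7 (7 adjusted over the list alone; IGHD 5.06 ± 0.42; limma's camera adjusted p = 9.05e-07, adjusted p = 0.16 with an estimated correlation). Marginal zone and memory B genes rose in 8 of 14 (11 adjusted over the list alone; TNFRSF13B 5.22 ± 0.47, CR2; limma's camera adjusted p = 4.28e-06, adjusted p = 0.135 with an estimated correlation). Plasma cell programme genes rose in 5 of 11 (6 up and 1 down adjusted over the list alone; MZB1 3.32 ± 0.44, DERL3 2.88 ± 0.49; limma's camera adjusted p = 0.0156, adjusted p = 0.395 with an estimated correlation). Naive B genes rose in 4 of 10 (5 up and 1 down adjusted over the list alone; FCER2, IGHD; limma's camera adjusted p = 0.0284, adjusted p = 0.212 with an estimated correlation).

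The other 9 called lists were down in B cells. All 13 cytotoxic effectors fell (13 adjusted over the list alone; CST7 -7.82 ± 0.31, PRF1 -6.86 ± 0.30; limma's camera adjusted p = 8.93e-17, adjusted p = 0.0924 with an estimated correlation). The regulatory T list fell in 11 of 14 (11 adjusted over the list alone; FOXP3 -9.19 ± 0.40, CTLA4 -8.20 ± 0.39; limma's camera adjusted p = 4.47e-10, adjusted p = 0.0924 with an estimated correlation). Costimulatory receptors fell in 8 of 11 (10 adjusted over the list alone; CD40LG, ICOS -7.70 ± 0.49; limma's camera adjusted p = 2.59e-09, adjusted p = 0.0924 with an estimated correlation). Checkpoint receptors fell in 7 of 11 (8 adjusted over the list alone; CTLA4, TIGIT -5.02 ± 0.35; limma's camera adjusted p = 2.49e-05, adjusted p = 0.0924 with an estimated correlation). Naive and central memory T genes fell in 7 of 13 with 1 up (7 and 1 adjusted over the list alone; MAL -9.90 ± 0.41, LEF1 -8.29 ± 0.30; limma's camera adjusted p = 5.86e-05, adjusted p = 0.135 with an estimated correlation). Chemokines and cytokines fell in 5 of 14 (5 adjusted over the list alone; CCL5 -7.44 ± 0.37; limma's camera adjusted p = 0.000185, adjusted p = 0.135 with an estimated correlation). T follicular helper genes fell in 6 of 11 and rose in 2 (6 and 2 adjusted over the list alone; SH2D1A -7.58 ± 0.42; limma's camera adjusted p = 0.00355, adjusted p = 0.276 with an estimated correlation). Chemokine receptors fell in 5 of 14, CXCR6 (-8.77 ± 0.30) among them, while CXCR5 rose (1.91 ± 0.20; 7 and 1 adjusted over the list alone; limma's camera adjusted p = 0.00488, adjusted p = 0.335 with an estimated correlation). Tissue residency genes fell in 2 of 9 (5 down and 1 up adjusted over the list alone; CXCR6, ZNF683 -7.70 ± 0.65; limma's camera adjusted p = 0.021, adjusted p = 0.296 with an estimated correlation).

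Among the lists that camera did not call in B against T cells, NF-kB targets rose in 5 of 16 and fell in 2 (CD83 3.23 ± 0.30, CD40 4.71 ± 0.61; 5 and 4 adjusted over the list alone). B cell survival genes rose in 4 of 12 (TNFRSF13C 4.63 ± 0.63). CD80 was the 1 of 7 checkpoint ligands that rose (2.97 ± 0.43, adjusted p = 0.00561, edgeR, 4 of 4 samples), with CD274, which encodes PD-L1, at 0.89 ± 0.92 (adjusted p = 0.578, edgeR, 2 of 4 samples). Exhaustion transcription factors had 2 of 13 up and 3 down (EOMES -6.70 ± 0.26, TOX -3.90 ± 0.75). Germinal centre B genes had 1 of 6 up (ELL3 4.69 ± 0.45) and 2 down (MYBL1 -4.45 ± 0.71). Interferon response genes had 1 of 16 each way (OAS1 1.5 ± 0.22, IFI6 -1.19 ± 0.26) and the cell cycle list 1 of 15 up (MCM5 1.45 ± 0.21). The 16 immediate early and heat shock genes did not pass. Except for NF-kB targets, the counts adjusted over the list alone were the same for these lists. By fry 14 of 23 lists passed.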

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

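Of the tests reported here, those of CXCL13 by CD40LG counts, by its level in replicate 4 and by free RNA were chosen only after the result was seen. So was the comparison with the other NK markers. Among 125 sets of 4 sample values, 15 had 1 sample far from the other 3, where chance gives about 1 in 20. Monocyte and macrophage-like cells were 12.05% of replicate 4 against 1.12% to 2.64% in the others, and plasma-like cells 4.11% of replicate 2 against 0.23% to 0.79%. Replicate 3 had 7465 barcodes against 5140 to 5201. The more frequent light chain made up 74% in replicate 4 against 98.92% to 100%. MS4A1 was found in 73.92% of the B cells of replicate 2 against 97.91% to 99.64%. In replicate 2 the log2 ratio of CD8 to CD4 T cells was 2.13 for NKG7 (others 4.55 to 4.68), 0.694 for FCGR3A (4.58 to 5.09) and 1.116 for GZMH (4.07 to 4.22). Between PD-1 high and low CD8 T cells, ENTPD1 was 1.263 in replicate 3 (others 2.34 to 2.53), CHI3L2 3.45 in replicate 1 (1.46 to 1.63) and TYROBP -2.17 in replicate 3 (-3.08 to -2.96). GLUL was -5.155 in replicate 1 (-1.99 to -1.54) and KLRD1 -0.541 in replicate 4 (-2.05 to -1.83). Between B and T cells, TCL1A was 8.83 in replicate 4 (others 4.63 to 5.23) and DNASE1L3 10.149 in replicate 1 (4.56 to 5.5).

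CXCL13 was higher in PD-1 high CD8 T cells as well as in PD-1 high CD4 T cells. RNA free in the droplets would reach all cells alike, but the mean level over the samples in PD-1 low CD8 T cells was 0.257% of that in PD-1 high CD8 T cells, and lower in B cells; the highest value of a sample was 2.37 against 242.8 CPM, in replicate 3. In replicate 4 CXCL13 in PD-1 high CD8 T cells was at 1072% of its level in PD-1 high CD4 T cells (exact 95% interval 664% to 1840%, counting error only), which no share of CD4 T cells with that average level in the CD8 gate gives. In replicates 1 to 3, which would need shares of 12.8%, 4.45% and 5.12%, CD40LG had 0 counts where 3.11, 1.79 and 3.35 were needed (one-sided exact Poisson p = 0.0445, 0.166 and 0.0351), below the need in 2 of 3 samples. The planned test over 9 CD4 T cell genes, CD4 itself among them, argued against such cells in 1 of these 3 samples and was fixed beforehand in replicate 4 by its CXCL13 level; in replicates 2 and 3 the genes stood at a median of 4.46% and 6.1% of their CD4 level (8.23% and 9.62% without CD4), so CD4 T cells in the gate stay open for replicates 1 to 3, and no biological explanation was tested.

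NK cell genes were lower in PD-1 high than in PD-1 low CD8 T cells. NK cells in the PD-1 low CD8 gate could raise these genes in that class. The differences of TYROBP, GNLY and KLRD1 would need NK cells at 9.54%, 21.06% and 25.15% of it, by mean levels over the samples. By sample, the median need of these 3 genes was 37.6%, 14.4%, 10.2% and 15.1% in replicates 1 to 4. The planned test, whether T cell markers stayed above the level that such a share would leave, found this in 2 of 4 samples. That test left NK cells in the gate open. By mean levels over the samples, the other NK markers gave smaller shares, with intervals ending at 1.34% (SH2D1B) to 14.3% (KLRF1). The intervals of GNLY and KLRD1 began at 19.47% and 20.03%. The intervals cover counting error in the CD8 T cell sums only, not the spread between samples or that of the NK-like cells. TYROBP, GNLY and KLRD1 were picked because they fell, so larger shares for them could be foreseen. Within counting error, no single share of NK cells with the mean levels of the NK-like class gives GNLY, KLRD1 and the other markers. Whether NK cells were the only source of the GNLY and KLRD1 differences stays open. Of the protein-gated CD8 T cells, 0.8% were NK-like by RNA, a share not counted for PD-1 low cells alone. The NK-like class held 0.07% of the cells of replicate 2, against 2.42% at Leiden resolution 2, so it may miss NK cells. For TYROBP (7.96% to 11.18%) NK cells also stay open. Of the other markers, FCGR3A, XCL1, NCAM1 and KLRF1 had intervals reaching 9.54% and the rest did not. No biological explanation was tested.

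B cells grouped by sample: 98.8% of the neighbours of B-like cells came from their own sample against 33.3% by chance, and 86% against 25% for T-like cells. The first value is from 3 samples, without replicate 2, at 1705 cells each. The second is from 4 samples at 529 cells each, so the 2 are not directly comparable. A difference between libraries that acts on all cells would spread B and T cells alike. In protein-gated cells of 4 samples, the median spread between samples was 1.81 times as large in B as in T cells at equal cells and UMIs. The bound of 1.5 set beforehand was passed, but it took no account of the spread of the ratio itself, which was 1.19 without replicate 2 and up to 2.09 without another sample. Library differences and differences between the tumors thus cannot be told apart here, since each person is 1 library.

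Of the splits of the class sums, 8 part all 4 pairs, the real one included, which is too few for a share under 0.05. CD8 against CD4 T cells gave 519 genes (highest other 0), PD-1 in CD4 T cells 79 (0), PD-1 in CD8 T cells 41 (0), CD25 high cells 183 (2) and B against T cells 1731 (0), each reached by 1 of 8. For the interaction, at 0 genes, 8 of 8 gave as many. Splits that part only 2 pairs leave differences between people in the contrast; 2 of those 24 reached 79 or more genes for PD-1 in CD4 T cells (highest 129), and 3 that part no pair could not be fitted. For surface proteins, 1 of 100 assignments of class labels, the real one, gave 250 pairs and the highest other gave 33. Chance can thus be excluded for the number of pairs as a whole, but not for any single pair. The classes are cell types named from RNA of the same cells, so fewer pairs with shuffled labels could be foreseen.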

How the results depend on the processing

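Doublets removed at the expected rate, the settings of the protein-gated shares and the shares without single samples were chosen after seeing the data; the others were set before the data were examined. Counts of genes, pairs and lists were taken as the same within 1.5 times the main count, shares within 1 SD between samples, and rho within the SD of the single-sample values. By this measure 36 of the main values moved, 171 stayed the same and 0 reversed. Counts and shares have no sign that could reverse. Leaving out 1 sample cannot move a mean share by 1 SD here, so shares without single samples were the same by construction and do not test stability. Among the 171 are shares that moved by over 1.5 times within a wide SD: cycling-like cells were 1.17% without replicate 3, plasma-like 0.53% without replicate 2 and monocyte and macrophage-like 1.83% without replicate 4, and the CD4 to CD8 ratio was 0.96 without replicate 1. Of 3528 values for single genes and antibodies 3148 kept their side of the threshold, 380 fell below it and 0 reversed. These genes and antibodies were chosen as past the threshold, and those of the naming rule also for the same sign in every sample. Few reversals could thus be foreseen, and their absence does not test stability. Genes not tested under an alternative are not among the values: with equal cells 24 of 46 genes of the CD25 comparison entered. With no filter on low counts the numbers of genes were 1073 (CD8 against CD4 T cells), 389 (PD-1, CD4), 198 (PD-1, CD8), 94 (interaction) and 515 (CD25 high cells, where the median of all genes shifted by -0.217 and 18.1% of calls were higher, against 38.8%). Without the replicate block they were 105, 1, 2, 0 and 2, and 122 for surface proteins; the block moved the B against T cell count by less than 1.5 times. DESeq2 gave 49 for PD-1 in CD4 T cells and 1 for the interaction. Cells above the median of CD45RO gave 44 in CD4 and 2 in CD8 T cells (3 samples). The interaction gave 1 with equal cells, 4 with PD-1 quartiles and 1 with doublets by expected rate, and CD25 high cells gave 62 with equal cells (1529 genes tested). CD4 T-like cells were 11.18% with the strict cell filter, and the RNA and protein rho was 0.843 with protein gates. Of 51 gene list calls 0 held with camera's estimated correlation, and fry made 23. Except for fewer samples or fewer genes tested where stated, the cause was not tested.

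Leaving out each sample in turn gave 281 to 508 genes (CD8 against CD4), 18 to 190 (PD-1, CD4), 29 to 54 (PD-1, CD8), 0 to 3 (interaction), 70 to 125 (CD25 high), 1006 to 1806 (B against T), 187 to 233 surface protein pairs and a rho of 0.847 to 0.87. Gene lists were not rerun with samples left out. Assigning light chains at 90 percent left the major shares at 98.91%, 100%, 100% and 73.96%; the other light chain alternatives were not run, since that comparison could not be fitted, nor was CD25 above the 95th percentile (1 sample with 20 cells); the regulatory T-like class was absent at Leiden resolution 0.5 and with the strict filter. The CD25 high class held 24 to 35 cells per sample.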

Other observations

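All values in this part were looked at after the data were seen. CD4 T cells of replicate 2 held cytotoxic RNA: GZMH was at 166.9 CPM and CCL5 at 699.7 CPM beside NKG7 at 458.1 CPM, with 1 count of CD8A. The anti-PE antibody took 1.577% of antibody counts in replicate 4 and 0.128% to 0.331% in the other samples.

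Barcodes left out for a mitochondrial share over 15% held a smaller share of T cells than kept cells in replicates 1 to 3, most so in replicate 3. Of the 4400 left-out barcodes of replicate 3, 5.32% were T cells by antibody, against 23.07% of kept cells. The shares were 7.21% against 12.58% in replicate 1 and 7.22% against 16.3% in replicate 2. In replicate 4 they were 29.47% against 28.42%.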
